A study of Mus musculus with 12 samples.

How the data were processed

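RNA was measured in 12 subcutaneous Renca tumors of mice, 6 from each of the 2 groups named in the labels, all taken on day 14. Whole tumors were used, so each library mixes RNA of tumor cells and of the surrounding stroma. Per the labels' protocols, total RNA was purified on Qiagen RNeasy columns and libraries were made with the Illumina TruSeq RNA kit. The submitters' processing notes name CASAVA 1.8.2, TopHat 1.4.1, HTSeq, limma and the mouse genome build mm9. Settings, strand handling and the annotation release were not given in the sources used here. Without known strand handling, reads of overlapping and antisense genes cannot be told apart. Values of near-identical copies, such as the hemoglobin and MHC genes, are uncertain because it is not known how reads matching several copies were counted.

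The authors deposited 1 table of log2 values for 14496 Ensembl genes in 12 columns, each named for its sample. The values have the form of log2 CPM (read counts scaled to a common library size) with 0.5 reads added, as limma's voom gives. In every column, 2 to the power of the value was a whole number of reads plus 0.5, times 1 step per sample. This held for 100% of values within 0.001 of a read. The reads recovered this way were summed to give the depth, 53312559 to 66142468 reads per tumor. That depth makes counting error small for all but the lowest genes, so that the spread between tumors limits the precision. Every gene in the table had at least 1 CPM (log2 of 0) in at least 2 tumors, so genes below that level in this tissue were not analysed here. Gene symbols were taken from a newer annotation by identifier, which gave a symbol for 14004 genes and none for 492. No coordinates are given, because that annotation uses another build than the deposited table.

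The deposited log2 values were used without further scaling, since they already are on a log2 scale and need no pseudocount. Genes with a log2 CPM of at least 0 in at least 6 of the 12 tumors were kept, which left 14008 genes. Differences are given as tumors with an intra-kidney tumor minus tumors alone. Genes were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes variances with a trend on the mean level), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 32 gene lists were tested with camera (limma, preset correlation between genes of 0.01) where at least 5 members passed the filter, which held for 29 lists. Some genes belong to more than 1 list, such as 8 of the 27 tested chemokines and 5 of the 15 M1 genes. A list score per tumor was the mean log2 CPM over the tested members. Scores were compared with two-sided exact permutation tests over all 924 assignments of the tumors, whose smallest possible p is 0.00216, and adjusted over the 29 lists. Intervals of score differences are 95% intervals from the pooled spread between tumors.

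The groups, the tests, the filter, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The rule named the 10 genes of largest change in each direction past the threshold. If fewer passed, it named those of smallest p up to 10 per direction, given as values that did not pass. It also named up to 2 members of each list past the threshold, and a fixed set of genes of the immune and tumor response whatever their result. Gene models without a symbol were passed over. Results of some genes that the rule named are not reported here and were left out of the search for tumors standing apart. List members given as examples outside that rule were chosen after their values were seen. The plan left the test open until the unit was known, and the log2 unit set limma as the main test.

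The gene test was tested on simulated data for this comparison, with 14008 genes of which 200 were changed. It recovered 96% of the genes changed 2-fold and 79% of those changed 1.5-fold, with 13 false calls among 188. The simulated genes varied independently, and the changed ones were drawn at random. In the real tumors genes of a list correlated, at up to 0.94 among the called lists. Lymphocyte genes also varied more, with SDs of 1.56 and 1.06 for Cd8a against a median residual SD of 0.114. The shares recovered therefore do not carry over to such genes. Every pair of tumors within a group differed by far more than counting error (chi-square per degree of freedom of 13.2 to 164 over 30 pairs), so that no library was counted as a duplicate. Alternatives were other filters, quantile, median and trimmed-mean scaling, other variance models, sample weights, a replicate block, a covariate for muscle, fat and skin genes, other list tests and scores, and leaving out each tumor in turn. Limma voom on the recovered reads was added after seeing the data. Principal components were computed on the tested genes.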

Results

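The study measured RNA in whole subcutaneous tumors of Renca cells, a mouse renal carcinoma line of BALB/c origin. Of the 12 tumors, 6 grew while another tumor was present in the kidney and 6 grew alone. The series set out to examine how a tumor at a distant site, described there as immunosuppressive, relates to the transcriptome of a subcutaneous tumor. Each tumor gave 53312559 to 66142468 recovered reads, with 59829094 ± 3914472 beside an intra-kidney (IK) tumor and 59448962 ± 4277580 alone (SD, n = 6 each, exact permutation p = 0.879). The labels do not say whether each tumor came from a separate mouse, so p-values measure only the spread between these samples.

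Cytotoxic lymphocyte and T cell transcripts stood lower in the subcutaneous tumors that grew beside an IK tumor. All 16 tested genes of the cytotoxic lymphocyte and NK list had lower means, among them the granule proteases Gzma (-2.03) and Gzmb (-2.08), perforin Prf1 (-2.01) and the CD8 coreceptor gene Cd8a (-1.66), as log2 differences. Reads in the lowest tumor were 52, 4, 17 and 46 for these genes, so counting error adds most to Gzmb. At a mean of -1.50 log2 CPM with an IK tumor and 0.57 alone, Gzmb also lay near the filter. The list score was 0.29 ± 1.42 with an IK tumor and 1.99 ± 0.96 alone (log2 CPM, SD, n = 6 each), a 3.25-fold lower geometric mean with an IK tumor. The T cell list was lower in 15 of 15 members, by a mean of -1.27, with Cd3e at -1.24 and the surface receptor Cd5 at -1.59. The regulatory T cell list was lower in 6 of 7 members, by a mean of -0.95. Its lineage factor Foxp3 lay at -1.43, while Tnfrsf9, which encodes the costimulatory receptor 4-1BB, lay at 0.48 in the other direction (0.27 without replicate 6 of the IK group).

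Limma's camera with a preset correlation placed these lists below the other genes, with Benjamini-Hochberg adjusted p = 4.68e-11 for cytotoxic lymphocytes, 3.07e-09 for T cells and 0.00163 for regulatory T cells. None of these calls held when the correlation was estimated (limma, adjusted p = 0.39 with an estimated correlation for each of the 3 lists), and their estimated correlations between genes were 0.65 to 0.94. Adjusted over the list alone, 16 of the 16 cytotoxic genes passed 0.05, 0 of 15 T cell genes and 0 of 7 regulatory T cell genes, and 0 genes of these lists passed over all genes tested. The cytotoxic genes correlated at 0.94 and had unadjusted p-values of at most 0.0472 (limma), so they passed together and are not 16 separate results. Adjustment over 1 list also takes no account of the other lists. By exact permutation of tumors the cytotoxic score difference of -1.70 (95% interval -3.3 to -0.14) had p = 0.045 and an adjusted p of 0.23. Score differences of T cells (interval -2.6 to 0.042) and regulatory T cells (-2 to 0.09) had exact permutation p = 0.061 and 0.078, also with an adjusted p of 0.23. Tumors divided by 1.45 log2 units on this score: 5 of 6 tumors with an IK tumor scored at most 0.44, and 5 of 6 alone scored at least 1.88. Replicate 2 of the IK group (2.99) and replicate 6 of the alone group (0.34) lay on the opposite side. Leaving out either of them enlarges the difference because of that position. The p-values of such fits, here and below, hold only given the removal and do not cover the choice of tumor. Without replicate 2 of the IK group the cytotoxic difference was -2.24 (exact permutation p = 0.0065, adjusted p = 0.039), and 9 of the 16 genes passed over all genes (limma, Benjamini-Hochberg). Without replicate 6 of the alone group it was -2.03 (exact permutation p = 0.026, adjusted p = 0.11), and 0 of the 16 genes passed. T cell and regulatory T cell scores likewise had an exact adjusted p of 0.039 without the first tumor, with 5 of 15 and 1 of 7 genes passing, and of 0.11 without the second, with 0 passing. With an estimated correlation, 0 lists were called without either tumor (limma, smallest adjusted p = 0.3 and 0.32).

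**Figure D1:**
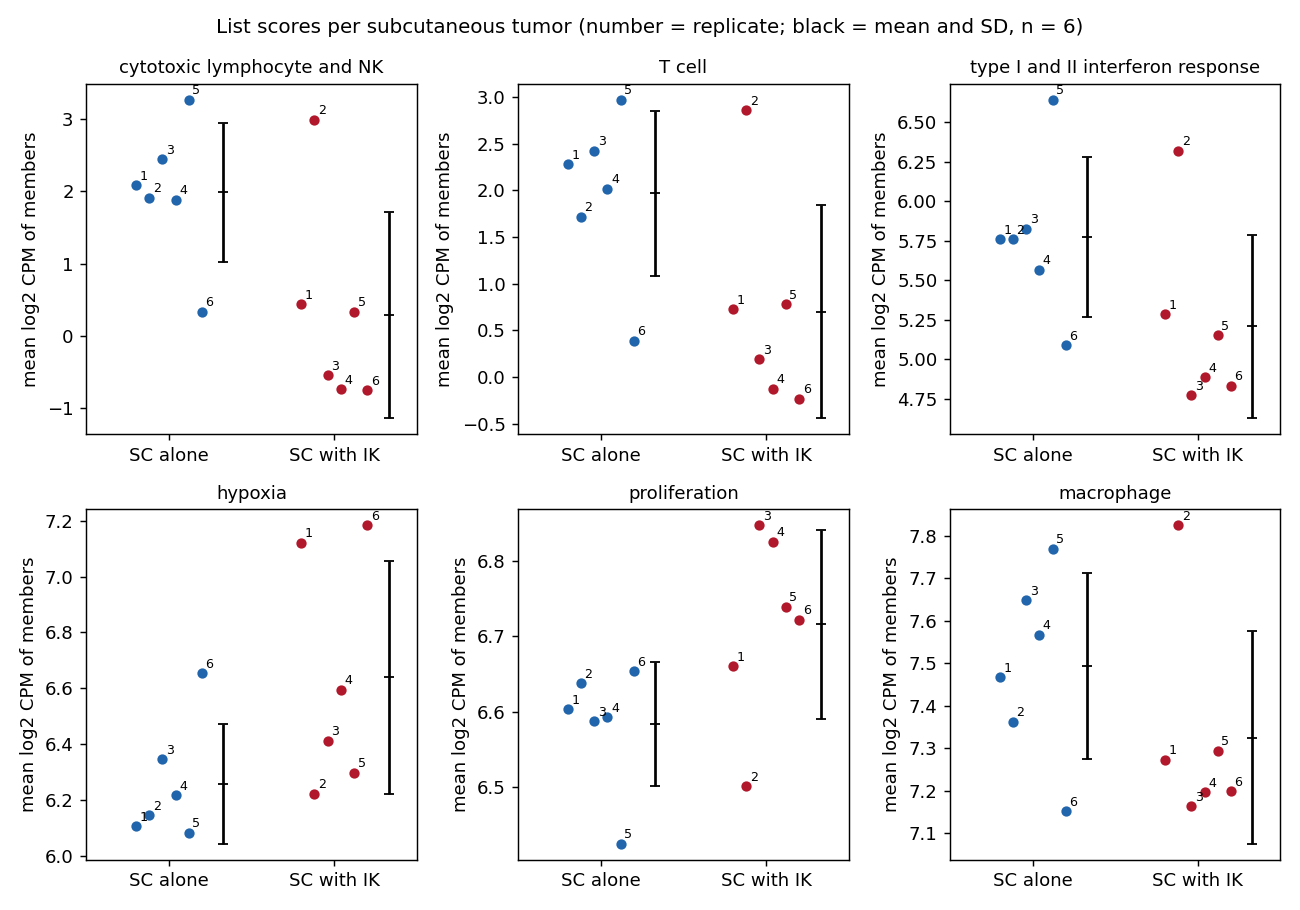
Scores of 6 gene lists in each tumor (vertical axis, mean log2 CPM of the tested members), by group on the horizontal axis, with replicate numbers beside the points and black bars for the mean and SD (n = 6). In the cytotoxic panel, 5 tumors with an IK tumor lie at or below 0.44 and replicate 2 at 2.99, while 5 tumors alone lie at or above 1.88 and replicate 6 at 0.34.

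Genes of antigen presentation and of the interferon response were lower in the same comparison. All 28 tested interferon response genes had lower means with an IK tumor (mean difference -0.57), among them the interferon-induced GTPase Gbp2 (-1.43). MHC class I presentation was lower in 15 of 15 genes (mean -0.47), including its transactivator Nlrc5 (-0.87) and the heavy chain gene H2-K1 (-0.46). MHC class II presentation was lower in 12 of 12 genes (mean -0.53), with H2-Ab1, a chain of the class II molecule, at -0.63. Camera (limma) gave Benjamini-Hochberg adjusted p = 5.35e-10, 7.35e-09 and 9.24e-07 for the 3 lists. These calls were lost as well, with adjusted p = 0.39 with an estimated correlation for each, and 0 members passed when adjusted over the list alone. Exact permutation p-values of the scores were 0.10, 0.065 and 0.078 (adjusted p = 0.25, 0.23 and 0.23). Replicate 2 of the IK group stood apart in all 3 scores. Without it the differences were -0.79, -0.64 and -0.74 (exact permutation adjusted p = 0.039 for each), and 6, 9 and 5 members passed over all genes (limma, Benjamini-Hochberg), against 0 with all tumors. Without replicate 6 of the alone group the exact adjusted p was 0.11 for each and 0 members passed, and with an estimated correlation 0 lists were called without either tumor (limma, smallest adjusted p = 0.3 and 0.32).

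Further lists of immune genes had lower means. The pan-leukocyte list was lower in 15 of 15 genes by a mean of -0.29, and the dendritic cell list in 15 of 15 by -0.48, with the chemokine receptor Xcr1 of cross-presenting dendritic cells at -0.79 and the plasmacytoid marker Siglech at -1.21. The general macrophage list was lower in 18 of 20 genes, by a mean of -0.17, or -0.27 without replicate 2 of the IK group. The alternatively activated (M2) list differed by a mean of -0.21 and a median of -0.11 (13 of 16 lower). Scored by the median over members in each tumor, which follows its genes of middle level, it turned to 0.09. Its mean was -0.32 without replicate 2 and -0.12 without replicate 4 of the IK group, and -0.12 without replicate 5 and -0.34 without replicate 6 of the alone group. A few members carried the means of the next 3 lists. The classically activated (M1) list differed by a mean of -0.42 (-0.64 without replicate 2 of the IK group) and a median of -0.18 (12 of 15 lower), and the checkpoint and immunosuppression list by -0.35 and -0.15 (14 of 18 lower). Chemokines differed by -0.49 and -0.22 (21 of 27 lower), with Cxcl9, an interferon-gamma-induced attractant of T cells, at -2.25, a member of the M1 list as well. Limma's camera called all 7 lists lower, with Benjamini-Hochberg adjusted p from 2.66e-06 for pan-leukocyte genes to 0.0214 for M1 genes. None held at an adjusted p = 0.39 for pan-leukocyte and dendritic, 0.45 for M2 and checkpoint, 0.51 for macrophage and 0.58 for M1 and chemokine lists, all with an estimated correlation. Adjusted over the list alone, 0 members of any of the 7 passed. Exact permutation p-values of the scores were 0.10 to 0.32 (adjusted p = 0.25 to 0.46). Replicate 2 of the IK group stood apart in the pan-leukocyte, macrophage and chemokine scores. Without it the M1, dendritic and chemokine scores had an exact adjusted p of 0.047, with 3, 0 and 5 members passing over all genes, and the other 4 lists one of 0.053 to 0.22. Without replicate 6 of the alone group the 7 lists lay at 0.11 to 0.15, and with an estimated correlation 0 lists were called without either tumor (limma, smallest adjusted p = 0.3 and 0.32). Chemokine, M1 and M2 calls also ended in limma without replicate 5 of the alone group (adjusted p = 0.0857, 0.124 and 0.105). M2 also lost its call without replicate 1 of the IK group (limma, adjusted p = 0.061), and M1 without replicates 3, 4 or 5 of that group or 3 of the alone group (adjusted p = 0.147, 0.0553, 0.0518 and 0.0588). Chemokine, M1 and M2 calls ended too with the covariate for muscle, fat and skin genes (limma, adjusted p = 0.15, 0.123 and 0.0683), and the M2 call with no filter (adjusted p = 0.0572).

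B and plasma cell genes had a score difference of -0.69 with 4 of 6 members lower and a median of -0.20. Jchain, the joining chain of secreted antibodies, at -2.86 and Fcrla at -0.95 carried the mean. Camera did not call this list (limma, Benjamini-Hochberg adjusted p = 0.0522; adjusted p = 0.39 with an estimated correlation), and its exact permutation p of 0.037 gave an adjusted p of 0.23, which was 0.039 without replicate 2 of the IK group and 0.11 without replicate 6 of the alone group. The neutrophil and granulocytic list differed by -0.06, with 6 of 10 genes lower, and was not called (adjusted p = 0.818, limma). Single tumors moved it from -0.16 without replicate 6 to 0.03 without replicate 5 of the alone group. The B cell list was called lower without replicate 1 or 5 of the IK group or 4 or 6 of the alone group (limma, adjusted p = 0.0257, 0.0498, 0.0257 and 0.0438), and 0 lists were called in these fits with an estimated correlation (smallest adjusted p = 0.32). It was also called with a replicate block (limma, adjusted p = 0.0431, against 0.39 with an estimated correlation and no block). Adjusted over the list alone, 0 members of either list passed.

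Cell cycle and hypoxia genes stood higher beside an IK tumor. All 24 tested proliferation genes had higher means, by 0.13 on average, including the mitotic kinases Cdk1 (0.19) and Bub1 (0.25). The score was 6.71 ± 0.13 with an IK tumor and 6.58 ± 0.08 alone (log2 CPM, SD, n = 6 each). Hypoxia genes were higher in 18 of 20 members by a mean of 0.38, with the vasoactive peptide gene Adm at 1.25, the mitophagy gene Bnip3 at 0.99 and the glucose transporter Slc2a1 at 0.71. Replicates 1 and 6 of the IK group had the highest hypoxia scores (7.12 and 7.18), and the other 4 of that group lay at 6.22 to 6.60, within the alone range of 6.08 to 6.65. Car9 (-0.06) and Pfkfb4 (-0.09), also hypoxia-inducible, went the other way. Camera (limma) gave Benjamini-Hochberg adjusted p = 4.53e-09 for proliferation and 4.56e-05 for hypoxia, and both lists were at an adjusted p = 0.39 with an estimated correlation. Adjusted over the list alone, 0 of 24 and 0 of 20 members passed. Exact permutation of the scores gave p = 0.065 and 0.076 (adjusted p = 0.23 for both). Without replicate 2 of the IK group, the proliferation difference was 0.18 (exact permutation p = 0.0022, the smallest possible there, adjusted p = 0.039). Without replicate 6 of the alone group it was 0.15 (exact permutation p = 0.061, adjusted p = 0.11), and without replicate 5 of that group, which stood apart with a low score, it was 0.10. With an estimated correlation 0 lists were called without any of these 3 tumors (limma, smallest adjusted p = 0.3, 0.32 and 0.48). Hypoxia did not pass without replicate 2 of the IK group or 6 of the alone group (exact adjusted p = 0.067 and 0.11).

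Immediate early genes, which respond to tissue handling as well as to signals, were higher in 16 of 19 members by a mean of 0.13, with Ier3 at 0.57. Red cell genes were higher in 5 of 5 members by a mean of 0.27, with the hemoglobin genes Hba-a1 at 0.34 and Hbb-bs at 0.32. Camera (limma) called both lists higher, at Benjamini-Hochberg adjusted p = 0.00167 and 0.00752, and both were at an adjusted p = 0.39 with an estimated correlation. Adjusted over the list alone, Ier3 passed as 1 of 19 and red cell genes as 0 of 5. Exact permutation of the scores gave p = 0.12 and 0.063 (adjusted p = 0.27 and 0.23).

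Fat cell genes were lower beside an IK tumor in 8 of 9 members by a mean of -0.67, with the lipid droplet gene Cidec at -1.82 and the hormone Adipoq at -1.15. Fibroblast and extracellular matrix genes were lower in 24 of 25 members by a mean of -0.27, which was -0.14 without replicate 5 and -0.43 without replicate 6 of the alone group, with the collagen gene Col1a1 at -0.37. Limma's camera called both lists (Benjamini-Hochberg adjusted p = 0.000413 and 0.00013), and neither held (adjusted p = 0.39 and 0.53 with an estimated correlation). Adjusted over the list alone, 0 members of either passed, and exact permutation p-values of the scores were 0.048 for fat cells (adjusted p = 0.23, but 0.047 without replicate 2 of the IK group and 0.11 without replicate 6 of the alone group) and 0.31 for fibroblasts (adjusted p = 0.46). Skeletal muscle genes were not called (adjusted p = 0.487, limma) and differed widely between tumors, with a score of -1.51 in replicate 6 of the alone group and 2.78 to 4.72 in the other 5. Without that tumor limma's camera called the muscle list lower (adjusted p = 9.26e-08), at a score difference of -0.98, but 0 lists were called there with an estimated correlation (smallest adjusted p = 0.32), and the score had an exact adjusted p of 0.11. With quantile normalization muscle was called lower too (limma, adjusted p = 0.0431, against 0.93 with an estimated correlation and no such scaling).

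Lists for the tumor cells themselves had mean differences near 0. The epithelial tumor cell score differed by 0.00 (95% interval -0.10 to 0.10), with the keratins Krt8 at -0.04 and Krt18 at -0.07. Scored by the median over members in each tumor, which follows genes of middle level such as Elf3 (0.35), it differed by 0.16. The median of the members' differences was -0.02, with 5 of 8 lower. The renal tubule score also differed by 0.00 (-0.10 to 0.094), with Cdh16, a kidney cadherin, at -0.13. Only the water channel gene Aqp2 (0.39), 1 of 7, passed in the renal list when adjusted over the list alone. Differences were -0.08 for endothelium and angiogenesis, -0.08 for epithelial to mesenchymal transition, 0.02 for oxidative phosphorylation and 0.03 for unfolded protein and amino acid stress. Scored by the median over members endothelium turned to 0.06, while the median of its members' differences was -0.11. Without replicates 1, 5 or 6 of the alone group endothelium was at -0.05, -0.02 and -0.14, and mesenchymal transition at -0.03, -0.01 and -0.16. With single tumors left out oxidative phosphorylation ranged from 0.00584 (without replicate 4 of the IK group) to 0.0429 (without replicate 3), and unfolded protein stress from 0.00755 (without replicate 5 of the alone group) to 0.0467 (without replicate 6). The TGF-beta response list had a mean of 0.00 and a median of -0.03, which differ in sign. Camera called none of these 7 lists (limma, Benjamini-Hochberg adjusted p from 0.0614 to 0.988), and apart from Aqp2 0 members passed when adjusted over the list alone. Calls appeared with single tumors left out, lower for endothelium without replicate 5 of the IK group or 2, 3 or 6 of the alone group (limma, adjusted p = 0.046, 0.0362, 0.0115 and 0.00281). Mesenchymal transition genes were called lower without replicate 6 of the IK group or 2, 3 or 6 of the alone group (limma, adjusted p = 0.0405, 0.0249, 0.0212 and 0.00684), and oxidative phosphorylation higher without replicate 3 of the IK group (adjusted p = 0.000978). With an estimated correlation 0 lists were called in any of these fits (limma, smallest adjusted p = 0.32), and with all tumors the 3 lists were at an adjusted p of 0.61, 0.6 and 0.62. Camera also called endothelium lower with quantile normalization or a replicate block (limma, adjusted p = 0.0474 and 0.0413) and mesenchymal transition lower with quantile normalization (adjusted p = 0.0346), against the same 0.61 and 0.6 with an estimated correlation and neither setting. The lists for T helper regulators, mast cells and eosinophils, and skin keratinocytes had 3, 3 and 1 tested members and were not tested.

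**Figure D2:**
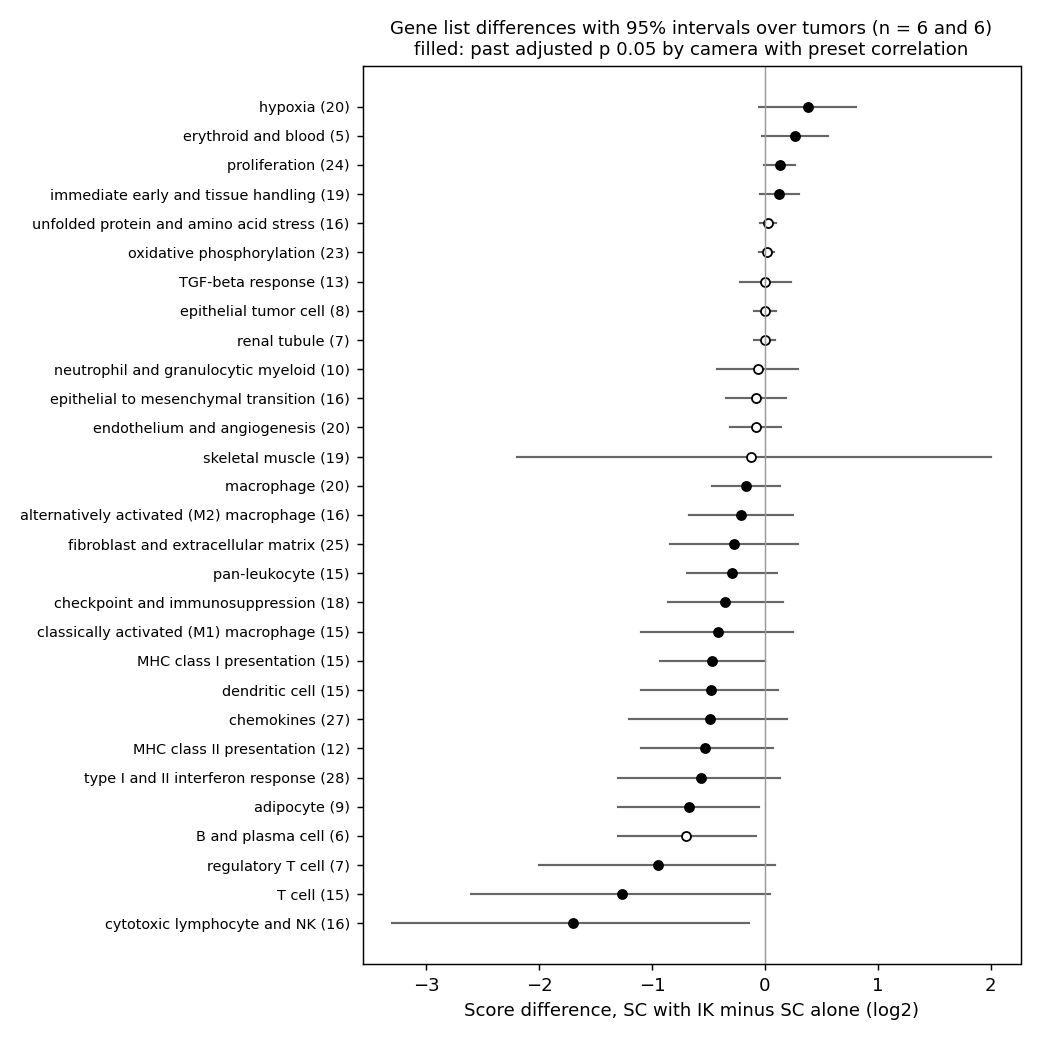
Score difference between tumors with an IK tumor and tumors alone (horizontal axis, log2) for each of the 29 tested lists, with 95% intervals over tumors (n = 6 and 6) and the number of tested genes in parentheses. Filled points mark the 19 lists that camera called with a preset correlation, from -1.70 for cytotoxic lymphocytes to 0.38 for hypoxia, of which 0 held with an estimated correlation.

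Among single genes, the smallest p-values belonged to modest differences. Papln, which encodes the extracellular matrix protein papilin, was higher beside an IK tumor by 0.84 ± 0.12 (log2, SE), at 0.56 ± 0.10 against -0.28 ± 0.22 log2 CPM (SD, n = 6 each; limma, Benjamini-Hochberg adjusted p = 0.171). The complement lectin gene Fcna followed at 0.63 (adjusted p = 0.366, limma). Genes of DNA replication and chromosome segregation were also among the 10 higher ones, with Gmnn, an inhibitor of replication licensing, at 0.15, the clamp loader subunit Rfc5 at 0.20 and the centromere gene Itgb3bp at 0.26. The remaining 5 were the linker histone Hist1h1c (0.26), the splicing factor Tra2b (0.21), Gm16332 (0.45), the mitochondrial arginase Arg2 (0.33) and the tetraspanin Cd9 (0.13). The lower ones were led by Iffo1 at -0.21 (adjusted p = 0.251, limma), followed by the formin Fhod1 (-0.22), the mitochondrial enzyme gene Mtfmt (-0.17), the collagen processing factor Pcolce (-0.14) and carboxypeptidase E, Cpe (-0.63). Leng8 (-0.31), Gmip (-0.21), Tmem80 (-0.25) and Ggt5 (-0.35) were also among them. Apart from Papln, Fcna and Iffo1, these genes shared an adjusted p of 0.432 (limma, Benjamini-Hochberg). Without replicate 2 of the IK group, Papln, Fcna, Hist1h1c, Tra2b, Gmnn, Cd9, Rfc5, Iffo1, Pcolce, Gmip and Ggt5 passed (limma, adjusted p = 0.0339 to 0.0486). The other genes given here did not. In Gmip and Tmem80, 1 tumor of a group stood apart from the other 5.

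Of the 14008 genes tested, 0 passed an adjusted p of 0.05 in limma, 0 passed 0.1, and 0 passed 0.05 in limma voom on the recovered reads. At an unadjusted p under 0.05 there were 1608 genes (821 higher, 787 lower) in limma and 1673 in voom, where chance gives 700. A difference of at least 1 log2 unit was seen for 141 genes, 5 higher and 136 lower. In 39 genes every tumor with an IK tumor lay above every tumor alone and in 28 every one lay below, 67 in all, where chance gives 0.216% or 30.3 genes over both directions together. That count was not taken for other divisions of the tumors, and genes correlate, so its excess over 30.3 was not tested. Without replicate 2 of the IK group, 171 genes passed (limma, Benjamini-Hochberg), 25 higher and 146 lower. Limma with sample weights, which gave that tumor the lowest weight (0.322) and so partly repeats its removal, called 545, 134 higher and 411 lower. Replicates 6 and 5 of the alone group also had low weights there (0.48 and 0.481), so these calls too rest on playing down single tumors. By exact permutation of list scores, 12 of 29 lists passed without replicate 2 of the IK group, 1 higher and 11 lower, against 0 with all tumors. Without any other single tumor, 0 genes and 0 list scores passed. The calls without replicate 2 are therefore conditional on removing a tumor that lay with the other group, and are no independent support.

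Regulators of immune suppression gave mixed values. The mannose receptor Mrc1 (0.02), nitric oxide synthase Nos2 (0.10) and the monocyte attractant Ccl2 (-0.04) turned in sign when single tumors were left out. Cd274, which encodes PD-L1, was at -0.35, the cytokine Tgfb1 at -0.05 and the angiogenic factor Vegfa at 0.15. The death receptor Tnfrsf10b lay at 0.09 and the costimulatory receptor Cd40 at -0.15. Single tumors moved these values. Vegfa was at 0.09, 0.23 and 0.07 without replicates 1, 2 and 6 of the IK group and Tnfrsf10b at 0.14 without replicate 2 of that group, while Tgfb1 was at -0.03 without replicate 4 and Cd40 at -0.09 without replicate 5 of the alone group. Adjusted p-values of all these genes and of Foxp3, Cd8a, Gzmb, H2-Ab1 and Tnfrsf9 lay between 0.432 and 0.941 (limma, Benjamini-Hochberg). Without replicate 2 of the IK group Foxp3 and H2-Ab1 passed (limma, adjusted p = 0.0475 and 0.0473) and the others did not. With sample weights Cd274, Foxp3, Cd8a, Gzmb and H2-Ab1 passed (limma, adjusted p = 0.0369 to 0.0469) and the others did not. Arginase Arg1 and interferon gamma, Ifng, did not reach the filter. Arg1 had 112 ± 95 reads per tumor with an IK tumor and 27.5 ± 12.9 alone, and Ifng 23.3 ± 44.6 and 63.3 ± 45.8 (SD, n = 6 each). Fitted without the filter, they differed by 1.71 and -2.72 log2 units (limma, adjusted p = 0.431 for both). Replicate 2 of the IK group had 114 Ifng reads and the other 5 had 1 to 12. Without it the mean was 5.2 reads and the difference -3.52 (limma, adjusted p = 0.0313), while without any other single tumor it was -3.06 to -2.26 (adjusted p from 0.194 to 0.76). Il10 is not among the genes of the table.

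On principal components, the first axis held 62.6% of the variance and the second 11.8%. Replicate 2 of the IK group (33 on the first axis) lay among the tumors alone, and replicate 6 of the alone group (-32.2) lay beyond all tumors with an IK tumor. Groups did not separate on either axis (exact permutation p = 0.121 and 0.0823).

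**Figure D3:**
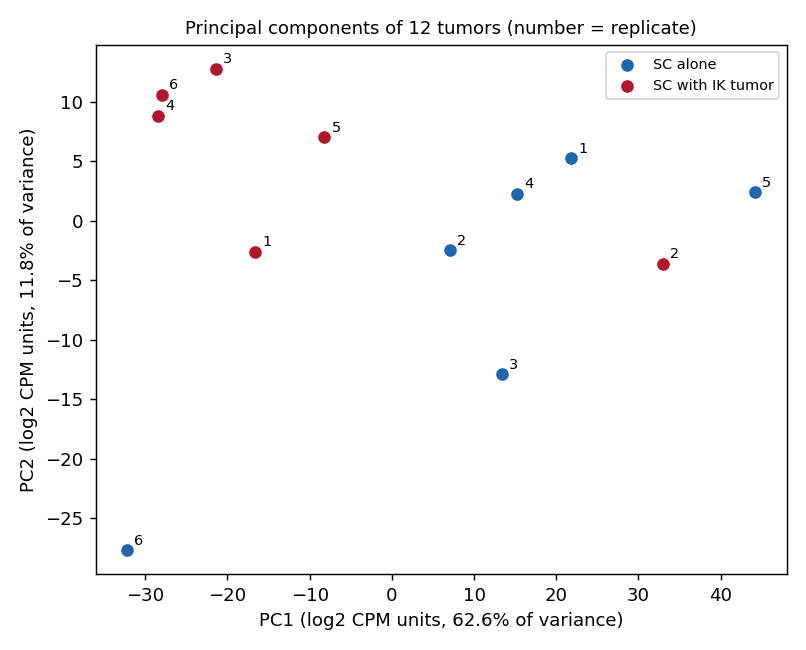
First and second principal components of the 12 tumors over the tested genes (both axes in log2 CPM units), colored by group and numbered by replicate. The IK group lies between -28.4 and -8.19 on the first axis except replicate 2 at 33, and the alone group between 7.09 and 44.2 except replicate 6 at -32.2.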

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

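The tests of exchanged labels, of a lower share of all leukocytes and of dilution were chosen only after the results were seen, and the others were planned. For the leukocyte share and dilution, a second reading by the median over members was added after the reading by the mean was seen, and agreement of both was then asked for. By the mean alone dilution would have been ruled out, and the rule asking for both did not decide it. The median over members in each tumor follows genes of middle level, however, and is not a median of the members' differences. For dilution, the median of the members' differences is therefore given below as well. In 16 of 122 groups of 6 values, 1 tumor stood apart from the other 5 by Dixon's ratio of gap to range, where chance gives about 1 in 20, or 6.1. These groups are not independent, since lists correlate and some of the genes are list members, so the excess over 6.1 was not tested. Replicate 2 of the IK group was the tumor standing apart in 12 of the 16. Its scores were high for pan-leukocyte (ratio 0.827), macrophage (0.802), cytotoxic lymphocyte (0.683), MHC class I (0.677), T cell (0.674), chemokine (0.671), interferon response (0.67) and MHC class II (0.668) genes. It was also high in Gmip (0.784), H2-Ab1 (0.659) and Foxp3 (0.646) and low in Tnfrsf10b (0.657). In the same group replicate 3 was low in Tmem80 (0.79) and replicate 6 high in Tgfb1 (0.639). Among tumors alone, replicate 6 was low in skeletal muscle genes (0.689), and replicate 5 was low in proliferation genes (0.708).

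Lymphocyte, interferon and MHC lists stood lower beside an IK tumor. Depth was alike in the 2 groups, so thinning all libraries to 53312559 reads, which moved no list difference by more than 0.011 and left the cytotoxic one at -1.69, was no test of it. A lower share of all leukocytes alike would lower macrophage genes as far. The cytotoxic difference between the groups went beyond the macrophage one by -1.53 (exact permutation p = 0.03, unadjusted, or -1.51 and p = 0.026 by the median over members). The cytotoxic list had the largest difference of the 29 lists in these same data, and the macrophage list differed by only -0.17. This p therefore largely repeats the exact permutation test of the cytotoxic score (p = 0.045, adjusted p = 0.23) and is no independent evidence. With single tumors left out the value of -1.53 became -1.97 to -1.33, with an exact p of 0.052 to 0.063 without replicate 3, 4 or 6 of the IK group or 3 or 5 of the alone group (0.052 by the median without the last) and under 0.05 otherwise. An exchange of the labels of replicate 2 of the IK group and replicate 6 of the alone group cannot be told apart from variation between tumors, since both lay inside the opposite group's range in 10 of 19 called lists and outside it, singly or together, in the rest. An effect of the IK tumor on lymphocytes, which may vary between tumors, stays open as a hypothesis beside these.

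Proliferation genes stood higher beside an IK tumor. The difference was 0.132 after thinning, which was no test of depth here either. Dilution by fewer stromal and immune cells would raise tumor cell genes as far as proliferation genes. The score difference was -0.00177 for epithelial tumor cell genes (interval -0.1 to 0.1, 5 of 8 lower). It was -0.00298 for renal tubule genes (interval -0.1 to 0.094, 5 of 7 lower). With single tumors left out, both stayed between -0.0327 and 0.0308, and the proliferation difference between 0.1 and 0.175. Proliferation genes exceeded epithelial tumor cell genes by 0.134 (exact permutation p = 0.035), but by the median over members the difference was -0.0249 (p = 0.82, exact). That score follows genes of middle level such as Elf3 (0.35), while the median of the epithelial members' differences was -0.0236. For the genes of these lists, the values argue against dilution as the source of the proliferation difference. The epithelial list has only 8 tested genes, and the proliferation score itself had an exact adjusted p of 0.23.

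Other divisions of the 12 tumors into 2 groups of 6 were drawn 100 times, the real one included. For genes past an adjusted p of 0.05 in limma, the real count was 0 and the highest other split gave 0. All 100 of 100 splits gave as many, which a count of 0 fixes in advance and which says nothing about chance. At an unadjusted p under 0.05, 10 of 100 splits gave as many as the real 1608, with 4145 in the highest other split, so chance is not excluded. Which tumors that other split put together was not examined. For lists called by camera with a preset correlation, 24 of 100 splits gave as many as the real 19, the highest other split gave 24, and 96 of the others called at least 1 list. Chance is therefore not excluded for the list calls either.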

How the results depend on the processing

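Limma voom on recovered reads was chosen after seeing the data, and the other alternatives were planned. The gene count of 0 past an adjusted p of 0.05 was also 0 under both other filters, 3 scalings, the robust variance model, the covariate for muscle, fat and skin genes, voom and an adjusted p of 0.1. It was 1 with no variance trend (Papln), 545 with sample weights, and 0 to 171 when single tumors were left out (171 without replicate 2 of the IK group, 0 without any other). The 19 list calls of camera became 0 with an estimated correlation per list and 0 in fry, and were 16 to 23 in the other settings. With an estimated correlation and 1 tumor left out, 0 lists were called in each of 12 fits. List scores gave 0 calls, also with standardized genes or medians over members, and 0 to 12 with single tumors left out (12 without replicate 2 of the IK group). A replicate block gave 0 genes, 21 lists and 0 scores. Little sign of pairing by number was seen, since tumors of one number correlated at -0.31 to 0.45, over 0.1 in 2 of 6, and 1 correlated best with its own number. With 62.6% of the variance on 1 principal component, such correlations could miss a weaker pairing. Directions turned for Mrc1 with sample weights (-0.018), Ccl2 with the covariate (0.0546), and the muscle list with the covariate, which contains it (higher, at 9.86e-11 in limma's camera). By the median over members, score differences turned for M2 macrophage (0.0854), endothelium (0.0563), epithelial tumor cell (0.164) and TGF-beta response (-0.0842) genes. Such scores follow the genes of middle level in a list. The medians of the members' differences were -0.112, -0.112, -0.0236 and -0.0258 for the same lists. With single tumors left out, Mrc1 ranged from -0.0539 to 0.0524, Nos2 from -0.15 to 0.403 and Ccl2 from -0.126 to 0.0388. Score differences ranged from -0.16 to 0.0295 for neutrophil, -0.98 to 0.266 for muscle, -0.0237 to 0.0191 for renal tubule, -0.0327 to 0.0308 for epithelial and -0.0586 to 0.0566 for TGF-beta genes. Apart from the covariate that contains the muscle list, the cause was not tested. DESeq2 and edgeR, planned if whole reads could be recovered, were not run although they could be, because the deposited unit is log2. Voom on those reads took their place. No other pseudocount was tried, since the deposited log2 values already hold 0.5 added reads. Depth limits the lowest genes, such as Ifng with 1 to 135 reads. Among the tested cytotoxic genes, Gzmk, Gzmb and Tbx21 had 2, 4 and 4 reads in their lowest tumors.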

Other observations

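Within the chemokine list, members went both ways. The neutrophil attractants Cxcl1 (0.32), Cxcl2 (0.35) and Cxcl3 (0.36) were higher beside an IK tumor as log2 differences and Cxcl5 (-0.22) was lower, while the interferon-induced Cxcl9 (-2.25), Cxcl10 (-1.27) and Cxcl11 (-1.80) were lower. The inflammatory cytokines Il1a (0.57) and Il1b (0.48) and the myeloid receptor Trem1 (0.59) were higher, and the neutrophil growth factor receptor Csf3r was at -0.45. None passed over all genes (limma, Benjamini-Hochberg adjusted p of 0.432 to 0.759). These genes were chosen after their values were seen and were not tested as a list.

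Arg1 reads were highest in replicates 1 and 6 of the IK group, with 200 and 260 reads, where the other 10 tumors had 8 to 77. The same 2 tumors had the highest hypoxia scores, 7.12 and 7.18, where the other 10 lay between 6.08 and 6.65. No test was run on this pair of values. Replicate 6 of the alone group, the lowest in muscle genes, had a hypoxia score of 6.65, the highest of its group.

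Because the cytotoxic scores fell into 2 clusters of 6 tumors, no correlation over all 12 is given. Within the clusters 8 relations were computed, of the cytotoxic score with the hypoxia, proliferation, muscle and fibroblast scores. The lowest p was that of the proliferation score in the upper cluster (Pearson's r = -0.95, exact permutation p = 0.0069, adjusted p = 0.055; Spearman's rho = -0.83, exact p = 0.058, adjusted p = 0.46). Without the 2 tumors farthest from the median, r was -0.55. In the lower cluster r was -0.73 (exact permutation p = 0.18, adjusted p = 0.46) and -0.92 without the 2 farthest.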
